A study of Arabidopsis thaliana with 4 samples.

How the data were processed

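Small RNAs were sequenced from immunoprecipitates of GFP-AGO1 and of GFP-AGO1ΔNES in inflorescences of Arabidopsis thaliana Col-0, with 2 libraries per form. Per the labels' protocols, each library came from an independent pool of several transformed lines. The tissue was frozen and ground, the lysate was precleared, and complexes were captured on magnetic GFP-Trap beads, a resin that binds GFP. RNA was then extracted with phenol and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie2 were used with the genome build TAIR10. The Bowtie2 version and its settings for mismatches and repeated matches are not given in the sources used here.

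Per the file headers, the deposited values are counts of reads per distinct sequence, 1 list per library. The values were whole numbers of at least 1 with different totals per library, and all sequences were 15 to 35 nt long. The lists gave no positions and no gene names. Positions and annotation were therefore obtained here by an exact match of each sequence to the NCBI TAIR10.1 assembly, and all coordinates are from that match. The matching was checked against a plain string search for 40 sequences, and all 40 gave equal numbers of matches. Of 3807920 distinct sequences over the 4 libraries, 2357299 had an exact match.

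The totals were 19511646 and 20327881 reads for GFP-AGO1 and 19673179 and 22364694 reads for GFP-AGO1ΔNES. Exact matches covered 89.7% and 89.5% of reads for GFP-AGO1, and 90.8% and 90.8% for GFP-AGO1ΔNES. Reads with more than 1 match made up 68.9%, 66.6%, 71.1% and 70.2%. A sequence with no read in a library has an upper limit of 3 counts, which is 1.54e-05%, 1.48e-05%, 1.52e-05% and 1.34e-05% of the 4 libraries in the same order. No molecular identifiers were present, so this limit and the exact binomial intervals (95%, Clopper-Pearson) cover counting error only. RPM values are reads per 1000000 reads in the total of each list. The log2 changes use TMM scaling instead, so they differ from the ratio of the RPM values.

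Mature miRNAs were counted by exact sequence. The annotation held 350 distinct mature sequences, of which 216 had a read. Reads of a sequence with several loci were counted once, so members of a family with the same mature sequence cannot be separated. Loci were counted with reads of 20 to 25 nt on either strand. Each read with several matches was shared equally among them, the middle base decided the locus, and sums were rounded. Overlapping loci both received a read, so their values are not independent, and PPR genes share many reads. MIR genes, tRNA, rRNA, snRNA, snoRNA and organelle genes were left out of this table. For class shares, each read went to the first class it matched in a fixed order from organelle genome and rRNA to unannotated sequence. The rRNA class included 4000 nt after the last annotated gene of each rRNA unit, because the annotation holds no 25S gene.

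Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05 over all features tested. Fold changes are GFP-AGO1ΔNES over GFP-AGO1 on the log2 scale, and standard errors (SE) were derived from the F statistic. There were 121 miRNAs and 6004 loci tested. Lists of loci and miRNAs were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. Shares were compared with an exact two-sided permutation test, which with 2 against 2 libraries cannot go below 0.333. DESeq2 1.42.0 was run as an alternative. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting and plots.

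The edgeR step was tested on simulated counts drawn from the real means. For 121 miRNAs with 20 changed, 10% of 2-fold and 80% of 4-fold changes were recovered, and 0% of 9 calls were false. For 6004 loci with 200 changed, 77.9% of 2-fold and 100% of 4-fold changes were recovered, and 2.27% of 176 calls were false. With no change simulated, there were 0 calls in either table.

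The design, the alternatives, the lists and the rule for naming were fixed before the data were examined. Named were the 10 most abundant miRNAs, and up to 8 miRNAs per direction past the threshold with the largest change, groups apart and a mean of at least 10 RPM. miR168a-5p, miR390a-5p, miR173-5p, miR393a-5p, miR172a, the TAS loci and AGO1 were named whatever their result. Up to 5 other loci per direction were named by the same kind of rule, with at least 50 reads on average, and up to 4 members per list. The lists were TAS loci, PPR phasiRNA loci, auxin receptor loci, small RNA pathway target loci, NB-LRR loci targeted by miR472 and miR825, 22-nt trigger miRNAs, nutrient and copper miRNAs, miRNAs with preference for other AGOs, floral and developmental miRNAs, and AGO and DCL feedback miRNAs.

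Alternatives covered the scaling, the test tool, the filter, read length, uniquely matching reads, the miRNA set, the 5′ window, the replicate number as a block and leaving out each library. The counts without miR165 and miR166 and the search for untemplated tails were added after seeing the data. A tailed read had no exact match and equalled a matching sequence of 18 to 26 nt followed by a run of up to 5 copies of 1 base. Tails per guide were tested with edgeR with the exact guide reads as offset, for guides with a mean of at least 1000 exact reads and at least 20 tailed reads in all. The replicates were separate pools, and their counts differed by more than sampling noise. No library from input RNA or from a mock immunoprecipitation was analysed here.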

Results

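Small RNAs bound to AGO1 were sequenced from unopened flower buds of Arabidopsis thaliana Col-0. AGO1 is the main Argonaute protein that carries plant miRNAs and many siRNAs of 21 and 22 nt. The plants carried a transgene with the AGO1 promoter and either GFP-AGO1 or GFP-AGO1ΔNES, a form without the nuclear export signal that the series title describes as nuclear localized. Endogenous AGO1 was also present in this ecotype. Each form had 2 libraries from independent pools of lines, with 19511646 and 20327881 reads for GFP-AGO1 and 19673179 and 22364694 reads for GFP-AGO1ΔNES. The comparison addresses which small RNAs AGO1 carries when it cannot leave the nucleus. Where the protein was located is not measured by these data.

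The bound small RNA was dominated in both forms by miR165 and miR166, which target HD-ZIP III transcription factor genes. miR165a-3p and miR166a-3p together made up 59.6% ± 0.895 of reads in GFP-AGO1 and 65.2% ± 0.662 in GFP-AGO1ΔNES (SD, n = 2). All mature miRNAs together made up 65.0% ± 1.65 and 69.9% ± 1.04. Reads from TAS loci, the non-coding sources of trans-acting siRNAs (tasiRNAs), were 3.89-fold lower in GFP-AGO1ΔNES, at 0.281% ± 0.00375 against 1.09% ± 0.136. Their share was 0.996% and 1.19% in the GFP-AGO1 libraries. It was 0.283% (exact binomial 95% interval 0.281% to 0.286%) and 0.278% (0.276% to 0.280%) in the GFP-AGO1ΔNES libraries. Protein-coding genes gave 3.57% ± 0.211 and 2.87% ± 0.0610 of reads, and pseudogene features gave 2.37% ± 0.122 and 2.43% ± 0.113. As a share of uniquely matching reads, a smaller total, the difference for protein-coding genes turned from -0.694 to 0.309 percentage points. The total changes too, so this turn cannot be read as one of protein-coding reads alone.

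Both forms mostly held 21-nt RNAs with a 5′ U, the profile known for AGO1. The 21-nt share was 73.7% ± 1.96 in GFP-AGO1 and 78.2% ± 0.762 in GFP-AGO1ΔNES, and the 24-nt share was 6.71% ± 1.36 and 7.17% ± 0.682. A 5′ U was found on 93.9% ± 2.15 and 96.0% ± 0.461 of reads. GFP-AGO1 replicate 1 stood apart in fragments of structural RNA. Its rRNA share was 2.61%, against 0.514% in GFP-AGO1 replicate 2 and 0.272% and 0.340% in GFP-AGO1ΔNES. Its tRNA share was 0.658%, against 0.223%, 0.0522% and 0.0571% in the same order. With 2 libraries per form, the exact permutation test cannot give a two-sided p below 0.333, and no share was below that value. As a share of uniquely matching reads, the difference for mature miRNAs turned from 4.83 to -2.48 percentage points. The reads of miR165 and miR166 match several loci, so they leave both the count and the total.

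Among miRNAs, 6 rose and 1 fell in GFP-AGO1ΔNES, out of 121 tested with edgeR. The rises were miR5012, miR399a, miR399b, miR851-5p, miR168a-5p and miR858a, and the fall was miR157d. miR5012 (chromosome 2, 8432747 to 8432767) rose from 9.56 ± 2.28 to 27.8 ± 2.95 RPM (SD, n = 2), a log2 change of 1.82 ± 0.23 (SE, edgeR adjusted p = 0.00108). miR168a-5p, which targets the AGO1 transcript (first of 2 loci at chromosome 4, 10578652 to 10578672), rose from 520.3 ± 93.7 to 793 ± 66.5 RPM. Its log2 change was 0.88 ± 0.21 (edgeR adjusted p = 0.0290). miR157d (chromosome 1, 18026989 to 18027008) went from 24.1 ± 6.51 to 7.17 ± 0.852 RPM, a log2 change of -1.46 ± 0.24 (edgeR adjusted p = 0.00329). Its 20-nt sequence UGACAGAAGAUAGAGAGCAC is contained in that of miR157a-5p, so its reads cannot be separated from shortened reads of that miRNA.

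The other 4 rises were in miRNAs of varied function. miR399a (chromosome 1, 10227165 to 10227185) and miR399b, which respond to phosphate supply and target the PHO2 transcript, rose by 1.38 ± 0.22 and 1.03 ± 0.20 on the log2 scale (edgeR adjusted p = 0.00329 and 0.00722). miR851-5p (chromosome 3, 19659646 to 19659666) rose from 76.7 to 145.5 RPM, with a log2 change of 1.19 ± 0.20 (edgeR adjusted p = 0.00329). miR858a (chromosome 1, 26773695 to 26773715), which targets MYB genes, rose from 50.4 to 78.0 RPM, with a log2 change of 0.87 ± 0.22 (edgeR adjusted p = 0.0425). RPM values are scaled to file totals and these log2 changes by TMM. With file totals the log2 changes were 1.54 for miR5012, 1.12 for miR399a, 0.92 for miR851-5p and 0.77 for miR399b. They were 0.61 for miR168a-5p, 0.63 for miR858a and -1.75 for miR157d.

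The 10 most abundant miRNAs did not pass the test, and their log2 changes lay between -0.20 and 0.73. miR166a-3p was at 46.4% ± 1.06 of reads in GFP-AGO1 and 50.9% ± 0.952 in GFP-AGO1ΔNES. Its log2 change was 0.37 ± 0.47 (edgeR adjusted p = 0.654), and that of miR165a-3p was 0.32 ± 0.39 (edgeR adjusted p = 0.650). miR158a-3p had 21391 and 15960.2 RPM, with a log2 change of -0.20 ± 0.30 (edgeR adjusted p = 0.717). miR159a, miR159b-3p, miR319a, miR396b-5p, miR398b-3p and miR403-3p had log2 changes of -0.03, -0.04, 0.23, 0.42, 0.57 and -0.04. miR162a-3p, which targets DCL1, had a log2 change of 0.73 ± 0.23 (edgeR adjusted p = 0.0973) and passed with DESeq2 and with other filters; miR398b-3p passed with DESeq2. miR390a-5p, the AGO7-bound trigger of TAS3, had 0.60 ± 0.21 (edgeR adjusted p = 0.125), and miR173-5p, the trigger of TAS1 and TAS2, had 0.18 ± 0.26 (edgeR adjusted p = 0.704). miR172a and miR393a-5p had -0.06 ± 0.31 and -0.02 ± 0.85 (edgeR adjusted p = 0.927 and 0.979).

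**Figure D1:**
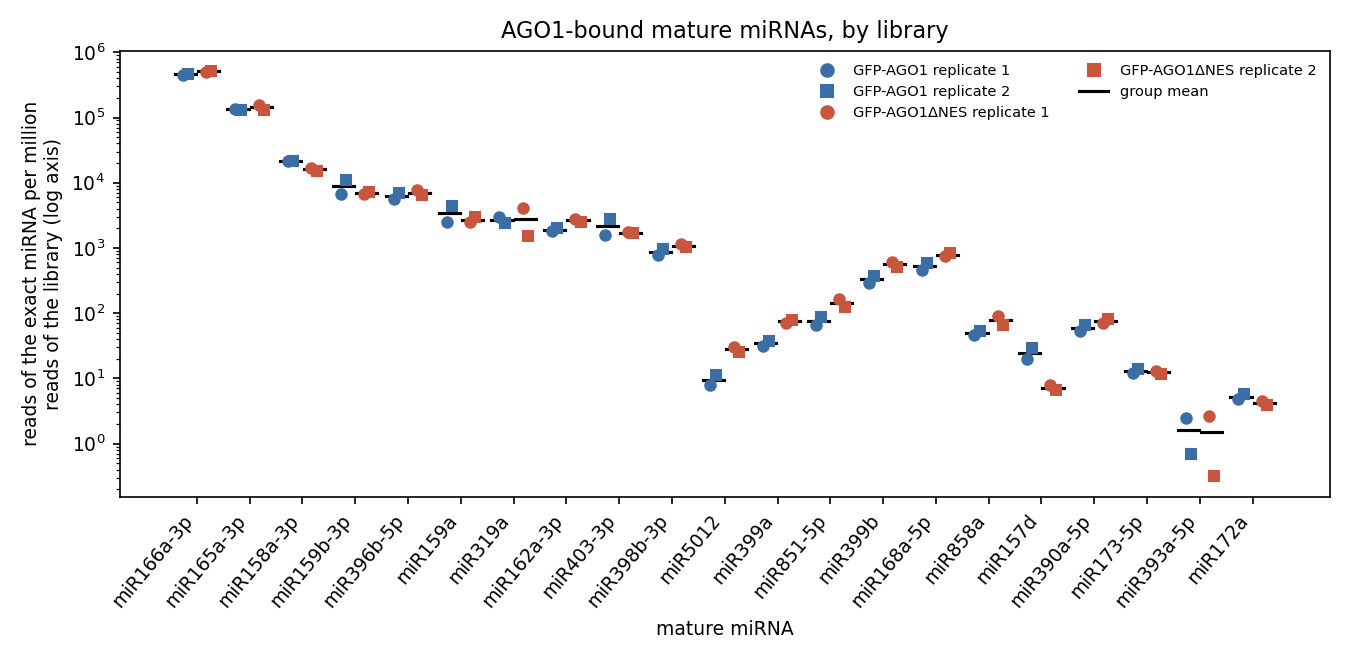
Reads of each exact mature miRNA (RPM, log axis) for the 21 miRNAs named by rule. Circles are replicate 1 and squares replicate 2 of GFP-AGO1 (blue) and GFP-AGO1ΔNES (red), and bars are group means; miR5012 lies at 7.94 and 11.2 RPM in GFP-AGO1 and at 29.9 and 25.7 RPM in GFP-AGO1ΔNES.

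By list, 2 of 9 nutrient and copper miRNAs rose, the phosphate-linked miR399a and miR399b, and the same number adjusted over the list alone. The copper-linked miR398b-3p and miR408-3p had log2 changes of 0.57 and 0.32 and did not pass. Camera gave this list an adjusted p of 0.0139, with an adjusted p = 0.390 with an estimated correlation and 0.0507 without GFP-AGO1 replicate 2. Of the AGO and DCL feedback miRNAs, 1 of 3 rose, miR168a-5p, and 2 rose adjusted over the list alone, with miR162a-3p (camera adjusted p = 0.129). Of 6 tested 22-nt trigger miRNAs, 0 passed in edgeR and 1, miR771, rose adjusted over the list alone (camera adjusted p = 0.459). In that list, 2 had an unadjusted p under 0.05 and 1 passed in DESeq2. Of 8 miRNAs with preference for other AGOs, 0 passed in edgeR, over all or adjusted over the list alone, 1 had an unadjusted p under 0.05 and 0 passed in DESeq2 (camera adjusted p = 0.867). Of 16 floral and developmental miRNAs, 0 passed in edgeR, over all or adjusted over the list alone, 2 had an unadjusted p under 0.05 and 2 were lower in DESeq2. The floral list had a median log2 change of 0.21 and a mean of 0.14, while camera put it down (adjusted p = 0.857) and fry up (adjusted p = 0.649).

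The median log2 change over all miRNAs was 0.18 with TMM, 0.0028 with the DESeq2 size factors and -0.12 with file totals. Relative to the TMM median, the changes were 1.64 for miR5012, 1.20 for miR399a, 1.003 for miR851-5p, 0.85 for miR399b, 0.70 for miR168a-5p, 0.69 for miR858a and -1.65 for miR157d. All 7 kept their direction under the 3 scalings, while the higher share of calls was 85.7% with TMM, 58.3% with size factors and 50% with file totals. Without GFP-AGO1 replicate 1 or replicate 2 there were 0 calls in edgeR (26 and 22 miRNAs with an unadjusted p under 0.05), and without GFP-AGO1ΔNES replicate 2 there was 1 rise and 0 falls (18 with an unadjusted p under 0.05). File totals left 1 rise and 1 fall, and counting by the 5′ end left 0 calls in edgeR (29 with an unadjusted p under 0.05).

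At other loci, siRNAs of TAS1, TAS2, PPR genes, AFB2, AFB3 and AGO1 fell in GFP-AGO1ΔNES, while the TAS3 loci did not pass. With edgeR, 84 of 6004 loci rose and 126 fell. The loci that fell had a median of 90.8% of reads at 21 and 22 nt, against 52.6% for those that rose and 45.9% for all tested. Over 80% of reads were of these lengths at 82 of the 126 falling loci and at 9 of the 84 rising loci.

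TAS1 and TAS2 transcripts are cut by miR173 and yield tasiRNAs, many of which target PPR genes. TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417) went from 2974 ± 421 to 417 ± 2.25 RPM (SD, n = 2), a log2 change of -2.84 ± 0.12 (SE, edgeR adjusted p = 1.74e-06). TAS1A (AT2G27400, chromosome 2, 11721539 to 11722468) had a log2 change of -2.77 ± 0.10 (edgeR adjusted p = 5.5e-07). TAS1B (AT1G50055, chromosome 1, 18549204 to 18550042) had -1.77 ± 0.09 (edgeR adjusted p = 4.42e-06). TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) overlaps AT2G39670 and went from 6129 ± 959 to 1427 ± 2.31 RPM, a log2 change of -2.11 ± 0.14 (edgeR adjusted p = 2.81e-05). At TAS1C, 70.2% of reads were the siRNA UUCUAAGUUCAACAUAUCGAC (chromosome 2, 16537816 to 16537836, minus strand), with 3702 and 4902 RPM in GFP-AGO1 and 1003 and 999.7 RPM in GFP-AGO1ΔNES.

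TAS3 transcripts are cut by miR390 bound to AGO7, and their tasiRNAs target ARF genes. TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437) had 579 ± 64.8 and 423 ± 55.5 RPM, a log2 change of -0.46 ± 0.13 (edgeR adjusted p = 0.103). It passed with uniquely matching reads, with no filter, with 24-nt reads only and without GFP-AGO1ΔNES replicate 1 (-0.66, edgeR adjusted p = 0.0049). TAS3b (AT5G49615, chromosome 5, 20134200 to 20134786) had -0.21 ± 0.10 (edgeR adjusted p = 0.380), and TASIR-ARF (AT5G57735, chromosome 5, 23394005 to 23394500) had 0.12 ± 0.13 (edgeR adjusted p = 0.837). The tasiR-ARF sequence UUCUUGACCUUGUAAGACCCC was at 61.5 and 60.9 RPM in GFP-AGO1 and at 69.6 and 48.1 RPM in GFP-AGO1ΔNES. TAS4 (AT3G25795) had too few reads to be tested. In all, 4 of 7 tested TAS loci fell, and 5 adjusted over the list alone (camera adjusted p = 2.69e-21, but adjusted p = 0.0823 with an estimated correlation). These directions were the same with TMM, size factors and file totals.

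All 15 tested loci of the PPR list fell, over all loci and adjusted over the list alone, with a median log2 change of -3.61. Apart from AT1G62860, annotated as a pseudogene, these genes encode RNA-binding proteins of mitochondria and plastids and yield secondary siRNAs after cleavage guided by miR161 and tasiRNAs. AT1G62910 (chromosome 1, 23298948 to 23301141) went from 52.6 ± 3.94 to 3.26 ± 0.0753 RPM, a log2 change of -4.02 ± 0.09 (edgeR adjusted p = 7.81e-08). RPF3 (AT1G62930, chromosome 1, 23306534 to 23308686) had -4.18 ± 0.13, AT1G63130 had -3.91 ± 0.10 and AT1G63070 had -3.79 ± 0.14. AT1G62914, a neighbour outside the list (chromosome 1, 23301315 to 23303162), had -4.20 ± 0.13. Members share reads, and only 13.1% of the reads of AT1G62910 and 8.52% of those of RPF3 matched 1 place. With uniquely matching reads, 13 of 13 fell with a median of -3.18. AT1G62860 had the smallest change, -0.58 ± 0.08, with 69.8% of its reads from a single 20-nt sequence and 26.9% of 21 and 22 nt. That sequence differs from miR158a-3p at 1 base. It had 1353 and 1371 reads in GFP-AGO1 and 1044 and 1087 in GFP-AGO1ΔNES. Exact miR158a-3p had 421549 and 430481, and 328319 and 340655. Reads of this locus thus cannot be separated from misread copies of miR158a-3p, and its fall cannot be taken as one of secondary siRNAs. Camera gave the list an adjusted p of 4.67e-88, with an adjusted p = 0.0823 with an estimated correlation.

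siRNAs at AFB2, AFB3, AGO1 and DCL1 also fell. AFB2 (AT3G26810, chromosome 3, 9867652 to 9870782) and AFB3 (AT1G12820, chromosome 1, 4368760 to 4371298, overlapping AT1G12810 and AT1G04977), auxin receptors targeted by miR393, had log2 changes of -1.73 ± 0.18 and -1.49 ± 0.16 (edgeR adjusted p = 0.000763 for both). TIR1 had -1.08 ± 0.33 (edgeR adjusted p = 0.135). Thus 2 of 3 fell, and 3 adjusted over the list alone (camera adjusted p = 2.65e-07, but adjusted p = 0.0823 with an estimated correlation). AGO1 (AT1G48410, chromosome 1, 17885633 to 17892632), the target of miR168, went from 894 ± 52.7 to 190.2 ± 40.4 RPM, a log2 change of -2.25 ± 0.12 (edgeR adjusted p = 9.6e-06). The transgenes carry AGO1 sequence, so reads from the endogenous gene and from the transgene cannot be separated. DCL1, the miRNA-processing enzyme, whose gene overlaps AT1G01050 and AT1G03993, had -0.61 ± 0.10 (edgeR adjusted p = 0.00979), and AGO2 had -0.62 ± 0.30 (edgeR adjusted p = 0.404). Of the AGO2 reads, 58.3% were a 21-nt sequence that differs from miR403-3p only at its last base. These reads cannot be separated from misread copies of miR403-3p. Thus 2 of 3 small RNA pathway loci fell, over all and adjusted over the list alone, and 1 without GFP-AGO1 replicate 2 or with DESeq2 (camera adjusted p = 2.65e-07, but adjusted p = 0.0823 with an estimated correlation).

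Of 5 NB-LRR immune receptor genes targeted by miR472 and miR825, 1 fell, and 2 adjusted over the list alone. This was AT5G43740 (chromosome 5, 17564697 to 17569148, overlapping AT5G43745), with a log2 change of -0.79 ± 0.10 (edgeR adjusted p = 0.00272). AT5G38850, AT5G43730 and AT1G12290 had -0.56, -0.51 and -0.41 and did not pass. Camera gave the list an adjusted p of 0.00022, with an adjusted p = 0.117 with an estimated correlation.

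The largest rises among loci of at least 50 reads were of other kinds. AT1G14780 (chromosome 1, 5090809 to 5094152), which overlaps AT1G14790, rose from 2.05 to 10.0 RPM, a log2 change of 2.27 ± 0.16 (edgeR adjusted p = 4.73e-05), and 75% of its reads were 24 nt. AT5G05905, a non-coding gene (chromosome 5, 15757451 to 15757709), rose from 90.6 ± 13.6 to 212 ± 40.1 RPM, by 1.22 ± 0.15 (edgeR adjusted p = 0.00221). At this locus 98.8% of reads were 21 or 22 nt, and 59.8% were the sequence CCGACACCGGAACUUAGGGCC (chromosome 5, 15757687 to 15757707, minus strand). AT5G24220, AT3G42130 and AT2G13845 rose by 1.03, 0.93 and 0.91. The last 2 share their most abundant sequence, overlap other genes, and had 7.04% and 2.67% of reads that matched 1 place. Leaving out a library gave 17 rises and 94 falls without GFP-AGO1 replicate 1, 36 and 89 without GFP-AGO1 replicate 2, 54 and 111 without GFP-AGO1ΔNES replicate 1, and 147 and 151 without GFP-AGO1ΔNES replicate 2. DESeq2 gave 44 rises and 83 falls, no filter gave 244 and 181, and 24-nt reads alone gave 11 and 31.

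**Figure D2:**
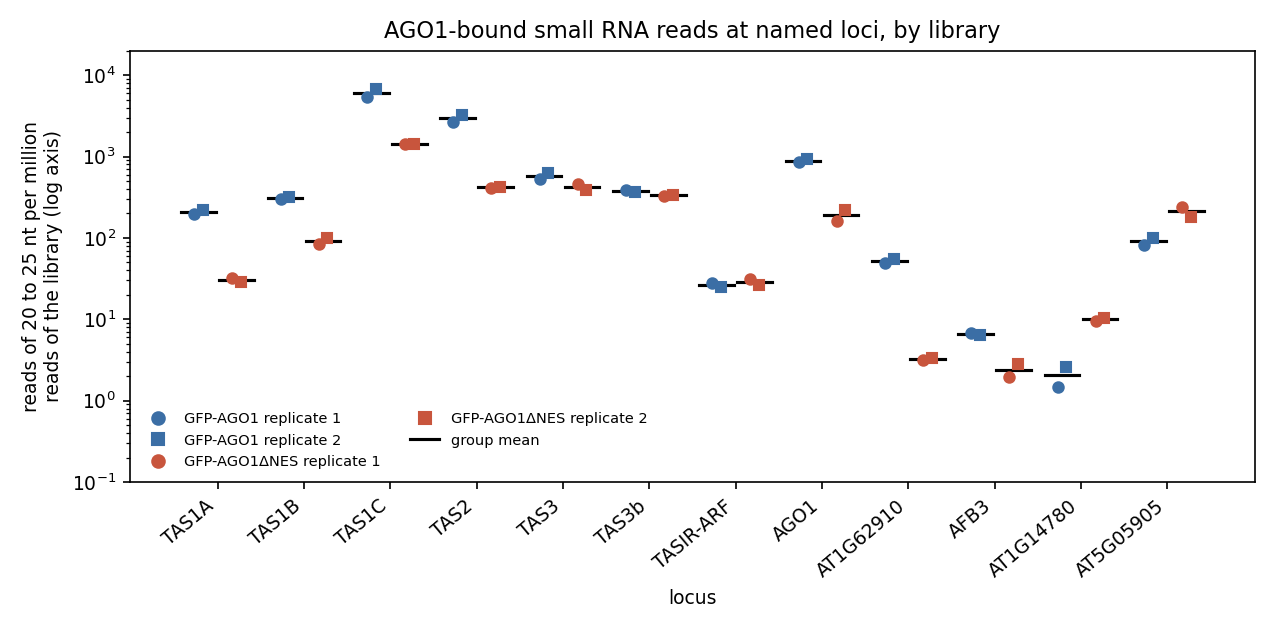
Reads of 20 to 25 nt (RPM, log axis) at 12 named loci. Circles are replicate 1 and squares replicate 2 of GFP-AGO1 (blue) and GFP-AGO1ΔNES (red), and bars are group means; TAS2 has means of 2974 and 417 RPM, while TASIR-ARF has 26.2 and 28.7 RPM.

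**Figure D3:**
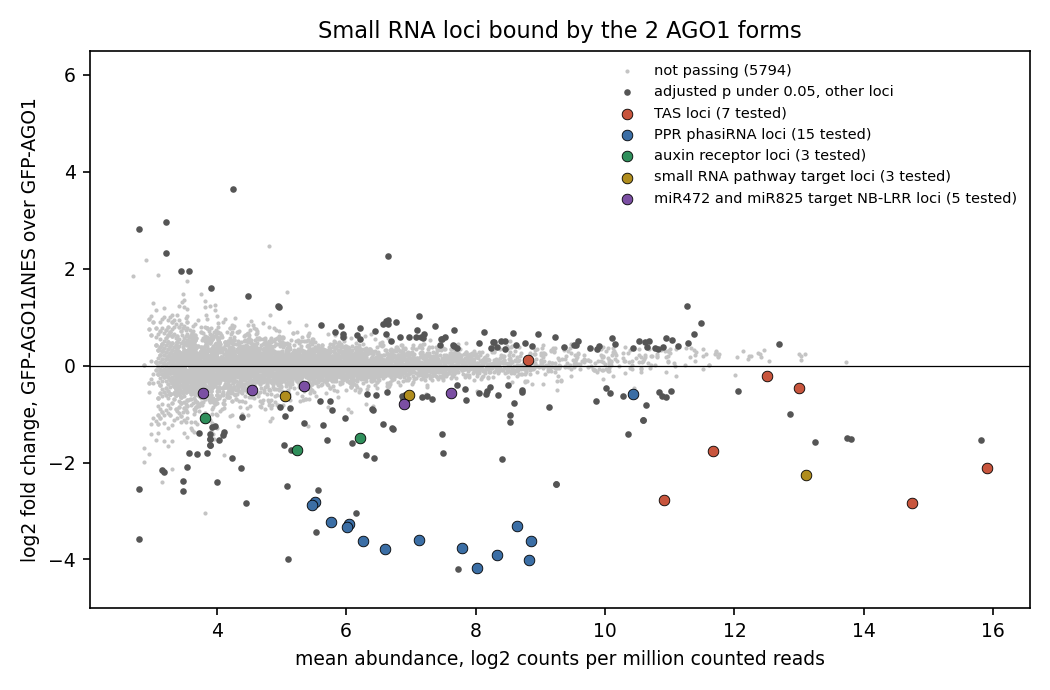
Log2 fold change of GFP-AGO1ΔNES over GFP-AGO1 against mean abundance (log2 CPM of counted reads) for the 6004 loci tested. Grey points did not pass, dark points passed in edgeR, and loci of the 5 lists are coloured whether or not they passed; all 15 PPR loci lie below 0.

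Passenger strands, the arms that are normally discarded during loading, made up 0.0485% ± 0.00955 of guide and passenger reads in GFP-AGO1 and 0.0325% ± 0.00121 in GFP-AGO1ΔNES (SD, n = 2), over 76 hairpin groups. Of 16 passengers tested, 0 passed in edgeR and 0 had an unadjusted p under 0.05, while 1 was lower in DESeq2, which gave no adjusted p for 12. Guides with another 3′ end that still matched the genome made up 2.87% ± 1.24 and 1.90% ± 0.104. Without miR165 and miR166, a count added after seeing the data, this share was 25.6% and 12.6% in the GFP-AGO1 libraries and 11.3% and 11.1% in the GFP-AGO1ΔNES libraries. Replicate 1 of GFP-AGO1 was thus the library with the most guides of altered 3′ end, and without it the difference over all guides went from -0.976 to -0.1005 percentage points. The exact permutation p was 0.333 for both shares, the smallest that 2 against 2 libraries can give.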

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

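The search for untemplated tails, and the tests that compare guides, were chosen after the data were seen; the tests on other RNA classes and on the pooled shares of C and G were written before their results were known. The results below lie in reads that the comparisons above do not use, those with no exact genomic match. The pooled counts exceed the limit of 3 counts; the A-tailed counts of miR396a-5p, miR851-5p and miR858a do not in at least 1 GFP-AGO1 library.

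Reads with no exact match made up 10.4% ± 0.150 of GFP-AGO1 reads and 9.16% ± 0.00827 of GFP-AGO1ΔNES reads (SD, n = 2). Among them, mature miRNAs followed by untemplated A were 5.29-fold more frequent in GFP-AGO1ΔNES, at 0.0629% ± 0.00451 against 0.0119% ± 0.000793 of mature miRNA reads. The shares of single guides that follow are of exact plus A-tailed reads, without other 3′ ends. Their folds are edgeR estimates of tailed reads relative to exact reads, so they differ from the ratio of the shares. miR159a with added A reached 4.90% ± 0.237 in GFP-AGO1ΔNES from 0.116% ± 0.0247 in GFP-AGO1, a 45.1-fold rise (edgeR adjusted p = 4.2e-06). Those of miR403-3p, miR165a-3p and miR166a-3p rose 11.7-fold, 5.74-fold and 1.87-fold. miR396a-5p went from 0.0219%, with 1 tailed read in each GFP-AGO1 library, to 0.888%. The highest share was that of miR161.2, from 1.49% ± 0.0386 to 29.4% ± 3.95, a 27.5-fold rise (edgeR adjusted p = 1.36e-05). Most reads from the 5′ end of miR161.2 had another 3′ end. Of all reads from that 5′ end, those with added A were 0.153% in GFP-AGO1 and 5.52% in GFP-AGO1ΔNES. Of 14 guides tested for A, 12 rose in edgeR. All 14 had both GFP-AGO1ΔNES libraries above both GFP-AGO1 libraries, which chance gives for 16.7% of guides. The guides share the same 4 libraries, so they are not independent and all 14 could separate together. Added U rose at 1 and fell at 1 of 18 guides, added C fell at 2 of 13, and added G rose at 4 of 9.

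The tables argue against 1 or 2 miRNAs being the only guides that rise, since the median log2 change over the 14 guides was 1.93. In reads, though, miR159a (2598 and 3259) and miR165a-3p (2894 and 3150) held most of the 8295 and 10221 A-tailed reads in GFP-AGO1ΔNES. An equal rise of every added base is argued against, since C had a median of 0.047 (SD 0.56 over 13 guides) and U a median of 0.045 over 18 guides. A general rise of 3′ additions or read errors would have to spare both U and C. One that does so cannot be told apart, since G on mature miRNAs had a log2 ratio of 1.22. The pooled ratio of C decides nothing, as 82.5% of C-tailed reads lay on miR158a-3p. An artefact adding A alike to every guide would give like gains, but gains in the share of all reads from the 5′ end of the guide ran from 0.00586 to 5.37 percentage points. Of 14 guides, 7 lay more than 2 times above or below the median gain of 0.258 by more than 2 times the SE of their own gain, just at the bound. An artefact adding A to every RNA cannot be told apart from the pattern, since A on rRNA fragments had a log2 ratio of 1.91, beside 2.40 on mature miRNAs, 0.67 on tRNA fragments and 1.02 on organelle fragments. The log2 ratio for A was 2.68 on reads of TAS loci and 2.04 on other reads of MIR genes. More added A was thus not limited to mature miRNAs. A difference in how guides are modified or protected in the 2 AGO1 forms may also account for the rise and was not tested.

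A 19-nt form of miR158a-3p with 1 added U (UCCCAAAUGUAGACAAAGCU) made up 28.9% ± 0.328 of it and the exact 20-nt miRNA in GFP-AGO1, 6.89-fold more than the 4.19% ± 0.450 in GFP-AGO1ΔNES (SD, n = 2). The 19-nt form without added U was itself 4.07-fold more frequent in GFP-AGO1, at 3218 ± 1394 against 790 ± 418 RPM. Per read of that form, reads with added U numbered 2.06 and 3.89 in GFP-AGO1 and 0.620 and 1.45 in GFP-AGO1ΔNES.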

How the results depend on the processing

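The counts without miR165 and miR166 were chosen after the data were seen; the other alternatives were planned. Of 153 values of named loci under planned settings, 144 kept direction and side of the threshold, 5 (of 127 of called loci) lost it, 3 gained it and 1 reversed: AGO1 with 24-nt reads only, at 0.51 (edgeR adjusted p = 0.621; 0.705% of its reads are 24 nt). Of 164 values of named miRNAs, 145 kept both, 15 (of 53 of called miRNAs) lost the threshold and 4 gained it. Leaving out a library ended 21 of the 28 values of the 7 called miRNAs: all without GFP-AGO1 replicate 1 or 2, all but 1 without GFP-AGO1ΔNES replicate 2 and 1 without GFP-AGO1ΔNES replicate 1. The cause was not tested, except that leaving out a library leaves fewer samples, with the lone library assumed to vary like the others.

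miRNA calls higher and lower, 6 and 1, became 7 and 5 with DESeq2 size factors, 1 and 1 with file totals, 10 and 9 with DESeq2, 9 and 8 with no filter, 10 and 7 with at least 50 reads in 2 libraries, 0 and 0 by 5′ end in edgeR (29 with an unadjusted p under 0.05), and 1 and 2 with the hand-written list. Leaving out a library gave 0 to 5 and 0 to 1. Locus calls, 84 and 126, became 44 and 83 with DESeq2, 244 and 181 with no filter and 11 and 31 with 24 nt only, where fewer loci (3959) were tested. Leaving out a library gave 17 to 147 and 89 to 151. Calls were 40% higher, against 57.4% with no filter.

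With the replicate number as a block, miRNA calls were 8 and 2 and locus calls 134 and 164. Deviations of same-numbered libraries correlated at 0.269 for miRNAs and -0.0038 for loci, and the labels give no shared origin for a number.

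With an estimated correlation, the lists lost their camera calls at the same medians: TAS -1.77, PPR -3.61, auxin receptors -1.49 and small RNA pathway -0.62 (all adjusted p = 0.0823), NB-LRR -0.56 (0.117) and nutrient miRNAs 0.41 (0.390). That estimate was 0.72 for PPR, but below the preset 0.01 for auxin receptors (-0.098), small RNA pathway (-0.0083) and NB-LRR (-0.069). With fry, TAS and PPR had an adjusted p of 0.0098. Auxin receptors, small RNA pathway and NB-LRR had a fry adjusted p of 0.0114, and nutrient miRNAs 0.126. The nutrient median was 0.19 to 0.46 with a library left out, and only without GFP-AGO1 replicate 2 was the call lost.

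Differences in share, in percentage points, changed from 4.43 to -0.0856 (21 nt) and from 0.463 to 5.09 (24 nt) with distinct sequences. As shares of uniquely matching reads, they changed from -0.811 to -3.52 for TAS and from 4.83 to -2.48 for mature miRNAs (3.44 with all reads of 20 to 25 nt). They reversed to 0.123 for other non-coding genes and to 0.309 for protein-coding genes. The total also fell, from 19511646 to 4054484 reads in GFP-AGO1 replicate 1, where TAS reads went only from 194349 to 187159. The TAS change thus rests largely on the smaller total, and the other changes cannot be told apart from it. The passenger difference was -0.0159, -0.0504 without miR166a-3p and -0.108 without miR165 and miR166; for 3′ variants it was -0.976, -2.98 and -7.88. Without GFP-AGO1 replicate 1 these differences were -0.0227 and -0.1005, and without replicate 2 -0.00917 and -1.85. The 24-nt difference was -0.498 and 1.42 without GFP-AGO1 replicate 1 and 2, and 0.946 and -0.0188 without GFP-AGO1ΔNES replicate 1 and 2, so its sign turned. That of pseudogene features, 0.0508, turned to -0.0354 and -0.0289 without replicate 1 of GFP-AGO1 and replicate 2 of GFP-AGO1ΔNES. The 5′ U difference of 2.04 was 0.521 and 3.56 without GFP-AGO1 replicate 1 and 2.

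The rare miR393a-5p had 49 and 14 reads in GFP-AGO1 and 53 and 7 in GFP-AGO1ΔNES.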

Other observations

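The target gene list, the loci singled out by abundance, and all tests on phasiRNA loci in this part were chosen after the result was seen; the 5′-end test of the 7 miRNAs was written before, with the comparison to its SE added after, and their fit without GFP-AGO1 replicate 1 was chosen after.

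Besides the lists above, siRNAs at developmental target genes of miRNAs and tasiRNAs were lower in GFP-AGO1ΔNES. Of 56 such genes, 26 had enough reads to be tested, 9 fell in edgeR, and 26 of 26 had a log2 change below 0. AP2, the floral identity gene targeted by miR172 (chromosome 4, 17400610 to 17403469), went from 4.87 ± 1.39 to 0.825 ± 0.161 RPM (SD, n = 2), a log2 change of -2.56 ± 0.24 (edgeR adjusted p = 0.000322). ARF4 (chromosome 5, 24308255 to 24312784) and ETT, auxin response factors targeted by TAS3 tasiRNAs, had -1.42 ± 0.10 and -0.92 ± 0.18. The leaf and petal growth regulators TCP3 and TCP4, targeted by miR319, had -1.30 and -0.92, HAM3 had -1.20, ARF6 had -1.18, SPL3 had -1.52 and ARF10 had -1.38. TCP3 and SPL3 overlap another annotated gene. The HD-ZIP III genes PHB, PHV, REV and ATHB15, targeted by the most abundant miRNAs here, had -0.41, -0.74, -0.28 and -0.36 and did not pass. The median of the 26 was -0.73, on the data in which the pattern was found, and no explanation of it was tested.

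Among the most abundant loci past the threshold, AT3G06435 (chromosome 3, 1968288 to 1970946) went from 5243 ± 641 to 1817 ± 172 RPM, a log2 change of -1.53 ± 0.15 (edgeR adjusted p = 0.0004). Of its reads, 17.7% matched 1 place, and the neighbouring AT3G00220, AT3G01845 and AT3G01835 had -1.51, -1.49 and -1.58. AT1G63630 had -2.45 ± 0.15 and AT3G07855 had -0.999 ± 0.14. PSEUDOSRKA (AT4G21370) had -0.53 ± 0.10. Rises at abundant loci were 0.89 ± 0.08 at AT1G08833, 0.64 ± 0.14 at AT5G39370 and 0.45 ± 0.10 at AT4G29654.

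The fall of secondary siRNAs at TAS1, TAS2 and PPR loci was set against several explanations. A lower share of the trigger among bound miRNAs is argued against at TAS1 and TAS2 by miR173-5p, with a log2 change of 0.18 ± 0.26. The absolute amount bound, and the amount on endogenous AGO1, were not measured. Less bound trigger stays open at PPR loci, where TAS1 and TAS2 siRNAs also act (TAS2 -2.84). miR161.1 and miR161.2 had -0.22 and -0.067 by exact sequence. By 5′ end they had -0.33 ± 0.30 and -0.98 ± 0.44 (edgeR adjusted p = 0.521 and 0.238). The last value may rest on GFP-AGO1 replicate 1, where 94.9% of reads from the 5′ end of miR161.2 had another 3′ end. This share was 84.7% in GFP-AGO1 replicate 2 and 86.9% and 85.3% in GFP-AGO1ΔNES. Scaling is argued against because the median of all loci was -0.00045 with TMM and 0.013 with file totals, beside -3.61 and -3.59 for the PPR list. The PPR median moved by 0.068 at most with file totals or without GFP-AGO1 replicate 1. That shift alone decides little, as the TMM factors lay between 0.88 and 1.13. Shared reads are argued against because the PPR median was -3.18 with uniquely matching reads. An even fall of all TAS loci is argued against by the log2 changes of the 7 tested loci, which spanned 2.96 (SE 0.18), with means of -0.18 at 3 TAS3 loci and -2.37 at 4 TAS1 and TAS2 loci. What stays open is that nuclear retention may limit the making or the loading of siRNAs whose precursors are cut by AGO1 itself, which bound RNA alone cannot separate and which was not tested. Endogenous AGO1 was also present in both sets of plants, and the precursors it cut were not measured.

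The 7 miRNAs that passed by exact sequence were set against 3′ shortening of guides in GFP-AGO1 replicate 1, which could lower exact counts. In the fit without that library, 7 of 7 kept their direction and the median in that direction was 1.02, against 1.19 with it (median SE 0.19). This passed the bound set for shortening as the whole cause, but cannot decide. The 7 were chosen on the same libraries, where the other GFP-AGO1 library already lay on that side of both GFP-AGO1ΔNES libraries. That shortening in GFP-AGO1 replicate 1 lowered the exact counts, in whole or in part, cannot be told apart from a difference between the forms. By the 5′ end the median was 0.95, which passed the bound set before, 75% of the exact value or 0.89, by less than its SE of 0.29. In edgeR 0 of the 7 passed without that library or by 5′ end (26 and 29 miRNAs had an unadjusted p under 0.05). A difference between the 2 AGO1 forms stays open and was not tested apart from other differences between the pools.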
